A study of Mus musculus with 49 samples.

How the data were processed

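Gene expression was measured in whole urinary bladders of female C57Bl/J mice that drank water with arsenate, an inorganic pentavalent arsenic salt, at 0, 0.5, 2, 10 or 50 ppm. Per the labels, mice were killed at an age of 76 days after 1 week or at 155 days after 12 weeks of exposure. Each of the 49 arrays holds the RNA of 1 mouse, without pooling, so p-values measure the spread between mice. All mice of a group share the first number of their label. What this number stands for is not given, and p-values cannot separate dose from it. RNA was extracted with Trizol, purified with a Qiagen method, labelled with biotin and hybridized to Affymetrix Mouse430_2 arrays, a 1-colour platform with several probe sets for many genes.

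The deposited values are linear intensity signals, 1 per probe set and array, and the submitters' processing notes name GCOS 1.0, the Affymetrix operating software. Its settings are not given in the sources used here. The values themselves showed a 2% trimmed mean of 500.003 to 500.004 on every array, so each array had been scaled to a common mean before deposit, and array quantiles still differed. For arrays, depth is not counted in reads, and the number of arrays per group limits the precision.

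The table held 45101 probe sets, of which 64 were control probe sets. The platform annotation gave 34958 probe sets a single gene, 932 several genes and 9160 none, and only single-gene probe sets were tested. These cover 18194 genes. Signals were taken as log2(value + 16), so the scale has a floor of 4 and the size of a change in a dim gene depends on the offset. A group mean under 5, where the signal is smaller than the offset, is called near the floor. Array medians spanned 0.458 on the log2 scale before the offset, below the preset limit of 0.5, and the values were therefore compared as deposited. A gene was kept if it lay above the 40th percentile of its array in at least 4 arrays, and was represented by its probe set of highest mean. This left 14624 genes.

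Each harvest was fitted alone, 24 arrays at 1 week and 25 at 12 weeks, with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, with a mean per group and the water group of the same harvest as control. A dose trend was fitted as a slope over dose ranks. The difference between harvests in the 50 ppm effect, the F test over all doses and the contrast between the water groups used all 49 arrays. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Adjusted p-values below come from limma unless another test is named. The 35 gene lists, 19 of pathways or responses and 16 of cell type markers, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Camera called 71 lists over the dose contrasts and the water contrast, and 0 with an estimated correlation. List members that were not measured or were dim are left out of each list's number. Single measures per array were compared between groups with two-sided exact permutation tests, adjusted over 136 tests against water and over 16 tests between the water groups. Tables were read with the R package data.table, version 1.17.8, and plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

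The groups, filters, 35 gene lists, alternatives and the rule for naming genes were chosen before the data were examined. So were the limma tests, the correlations of dose effects and camera for the dose contrasts and the water contrast. The liver, kidney and lung lists, the permutation tests of array measures and camera on the difference between harvests were not in that plan. The rule names, among called genes whose treated arrays all lie on one side of the control mean, the 10 largest rises and 10 largest falls at 50 ppm and between the water groups. Elsewhere it names the 5 largest each way, or the 3 genes of smallest p where none was called. It adds up to 4 members of each list spoken of and 8 arsenic-related genes at 50 ppm. For trends and differences between harvests no rule on sides applied.

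The steps were tested on simulated data with 14624 genes and known changes. For 50 ppm at 12 weeks, 49.3% of 1.5-fold, 79.1% of 2-fold and 97% of 4-fold changes were recovered, and 10 of 160 calls were false. For 50 ppm at 1 week the shares were 61.2%, 77.6% and 98.5%, and 13 of 171 calls were false. For the difference between harvests they were 23.9%, 53.7% and 92.4%. Of 35 simulated lists, camera called the 1 that had been shifted and 0 of the others. The simulated genes varied independently of each other. These rates therefore do not cover real genes or lists whose members move together from array to array.

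Alternatives were offsets of 1 and 64, quantile normalization, no filter, a filter at the 60th percentile, all probe sets, array weights, a 1.5-fold minimum, all arrays in 1 fit, the RNA integrity number as a covariate with the 2 arrays that lack it left out, arrays with an integrity number under 8 left out, the replicate number as a block, log2(ppm + 0.5) in place of dose ranks and leaving out each array in turn. Covariates for control probe sets and liver markers, and fits without 3 outlying arrays or without these 2 arrays, were added after seeing the data. Replicate numbers only name arrays, and no pairing was used. No 2 arrays held identical values, and the highest correlation between arrays was 0.9842. Liver, kidney, lung and other tissues of these mice were not analysed here.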

Results

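The study exposed female mice to arsenate in drinking water and followed gene expression in the urinary bladder, an organ that arsenic taken up with water reaches through the urine. Bladders were taken after 1 week or 12 weeks, at 5 doses each. Every group held 5 mice except 0.5 ppm at 1 week, which held 4. The RNA integrity number averaged 9.28 in the 1-week water group and 9.58 in the 12-week water group. It was lowest in the 2 ppm group of 1 week, with a mean of 8.16 and a range of 7.2 to 9.7, and was not given for 2 arrays of the 10 ppm group of 1 week. Changes are log2 differences from the water group of the same harvest ± SE, with 5 arrays a side unless stated. Signals are log2(value + 16) with a floor of 4, and a change from or to a group mean under 5, called near the floor below, depends on the offset in its size.

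At 12 weeks and 50 ppm, the highest dose, immediate early genes were lower than in water-drinking mice. Egr1, a transcription factor switched on within minutes by growth and stress signals, fell by 2.87 ± 0.34 (adjusted p = 7.81e-05). Its mean log2 signal was 12.60 ± 0.53 (SD, n = 5) in water and 9.73 ± 0.43 (SD, n = 5) at 50 ppm. Ccn1, a secreted matricellular protein long called Cyr61, fell by 2.84 ± 0.40 (adjusted p = 9.15e-04), and Fos, a subunit of the AP-1 transcription factor, fell by 1.88 ± 0.28 (adjusted p = 0.00196). The 4 probe sets of Ccn1 ran from -2.84 to -0.33, all lower, and 2 of them were called. The nuclear receptor Nr4a1 fell by 1.89 ± 0.51. Of the 28 measured immediate early genes, 9 fell and 0 rose over all genes tested, and adjusted over the list alone 16 fell and 1 rose. The list had a median change of -0.58 (camera adjusted p = 5.99e-08, and adjusted p = 0.833 with an estimated correlation). The poly-A spike level, read from control transcripts added before labelling, was 0.861 lower in this group than in water on the log2 scale (exact permutation p = 0.0159, adjusted 0.108). With it as a covariate, the mean change of the immediate early genes went from -0.719 ± 0.223 to -0.222 ± 0.297, 30.8% of its size.

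Smooth muscle markers were higher at the same dose. All 14 measured markers had a higher mean than in water, with a median change of 0.36. Only Synm, an intermediate filament protein, rose over all genes (0.96 ± 0.25), and 11 rose adjusted over the list alone. The camera adjusted p was 1.09e-06, and the adjusted p was 0.833 with an estimated correlation. The mean level of these markers per array was 13.33 against 12.93 in water, an exact permutation p of 0.00794 that was 0.0831 adjusted. It did not rise in the order of the doses. At 0.5, 2 and 10 ppm it lay 0.368, 0.0927 and 0.0706 above water (exact permutation p = 0.0159, 0.484 and 0.643, adjusted 0.108, 0.793 and 0.804). Myocd, the cofactor that drives the smooth muscle programme, was 0.59 ± 0.18 higher without passing the test (adjusted p = 0.0593). Among 15 glucocorticoid targets, Klf9 (1.14 ± 0.19), Zbtb16 (0.78 ± 0.21) and Tsc22d3 (0.58 ± 0.14) rose, and Dusp1 (-1.19 ± 0.24) and Mt2 (-0.51 ± 0.14) fell. Adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.0109, and adjusted p = 0.833 with an estimated correlation). Dusp1 is also an immediate early gene and Mt2 a metal-binding metallothionein.

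In the cell cycle list Pcna, the sliding clamp of DNA replication, rose by 0.40 ± 0.09, 1 of 38 measured members. Adjusted over the list alone 4 rose and 0 fell, with a median change of 0.27 (camera adjusted p = 0.0107, and adjusted p = 0.833 with an estimated correlation). The collagen and matrix list had 2 of 28 members that rose, the crosslinking enzyme Lox (0.93 ± 0.24) and the protease inhibitor Timp3 (0.53 ± 0.14), and the same number adjusted over the list alone. Its camera adjusted p was 0.0425, and its adjusted p was 0.833 with an estimated correlation. The list of epithelial to mesenchymal transition was called higher (median 0.15, camera adjusted p = 0.0316), with 0 of 25 members called over all genes or adjusted over the list alone, and adjusted p = 0.833 with an estimated correlation.

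Genes known to respond to arsenic or metals moved in both directions. Hmox1, the haem-degrading enzyme induced by oxidative stress, rose by 0.66 ± 0.15 (adjusted p = 0.0201), while Gstm2, a glutathione transferase, fell by 0.42 ± 0.11. They were the called members among 29 NRF2 targets, and Nqo1 stood at 0.41 ± 0.14 (adjusted p = 0.0781) and Gclm at 0.07 ± 0.08. The zinc exporter Slc30a1 (0.56 ± 0.15) and the metal-sensing factor Mtf1 (0.51 ± 0.14) rose, while Mt2 fell and Mt1 stood at -0.30 ± 0.13 (adjusted p = 0.154). As3mt, the enzyme that methylates arsenic, stood at -0.05 ± 0.14 (adjusted p = 0.844). In its list of 22 uptake and methylation genes, the aquaglyceroporin Aqp7 fell by 1.20 ± 0.34 to a mean of 4.711, near the floor. Among stress genes, Pdia4 (0.65 ± 0.19), a protein folding enzyme of the endoplasmic reticulum, and Pmaip1 (0.98 ± 0.23), a p53 target that promotes apoptosis, rose, and Ddit4 (-0.55 ± 0.11) fell. Cdkn1a stood at -0.23 ± 0.15, and 0 of 32 DNA repair genes were called. Adjusted over the list alone, 2 NRF2 targets rose and 2 fell, 3 metal response genes rose and 1 fell, 5 genes of the unfolded protein response rose and 2 fell, 1 p53 target rose and 2 fell, 1 uptake and methylation gene fell, and 0 DNA repair genes changed. None of these lists was called by camera (adjusted p from 0.665 for the metal response to 0.967 for p53 targets).

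Over all 14624 genes, limma called 594 at 50 ppm and 12 weeks, 335 higher and 259 lower, and 257 of these changed by at least 1.5-fold. Under quantile normalization the split was 271 higher and 286 lower. Among the called rises were Cidea, a lipid droplet protein (1.40 ± 0.40), Emb (1.39 ± 0.30), Cd209c (1.38 ± 0.36), Klf15, a metabolic transcription factor (1.37 ± 0.36), Lrch2 (1.24 ± 0.32), the glutamate receptor subunit Gria1 (1.21 ± 0.33), the sphingomyelin synthase Sgms1 (1.20 ± 0.20), Cenpq (1.18 ± 0.34) and Cmah (1.16 ± 0.34). The 4 probe sets of Cmah ran from -0.51 to 1.16 and those of Sgms1 from 0.45 to 1.20, and the 2 of Emb from 0.31 to 1.39 and of Gria1 from 0.23 to 1.21. The water mean of Cd209c was 4.514, near the floor. Klf15 stood at 0.89 without water replicate 5 and Cenpq at 0.77 without water replicate 2. The immunoglobulin segment Igkv15-103 was also called higher (3.70 ± 0.97), but its water mean of 4.715 lay near the floor, its 50 ppm arrays ran from 5.712 to 13.07. Besides the immediate early genes, called falls included Efcab3 (-1.57 ± 0.38), Traf3ip3 (-1.55 ± 0.39), Ccna1 (-1.52 ± 0.43), the histone demethylase Kdm4d (-1.42 ± 0.34), Cdsn (-1.38 ± 0.34) and the tight junction gene Cldn19 (-1.35 ± 0.40). At 50 ppm the means of Efcab3, Traf3ip3, Kdm4d and Cldn19 were 4.86, 4.74, 4.953 and 4.767, near the floor, and that of Ccna1 was 5.003. Hybridization controls were 0.494 higher than in water (exact permutation p = 0.00794, adjusted 0.0831). With the poly-A spike level as a covariate, limma called 1 gene, which was not among the 594. Of the 594 changes 515 were smaller with the covariate, 71 at least as large and 8 of opposite sign, and their median SE went from 0.135 to 0.184. Egr1 stood at -1.85 ± 0.43 (adjusted p = 0.122), Ccn1 at -2.27 ± 0.58 (adjusted p = 0.157) and Fos at -1.17 ± 0.38 (adjusted p = 0.272), while Cidea stood at 1.98 ± 0.58, Cd209c at 2.10 ± 0.51, Klf15 at 1.52 ± 0.54 and Hmox1 at 0.74 ± 0.21 (adjusted p = 0.212). The count was 1617 without water replicate 1, 47 without water replicate 2, 105 without water replicate 3 and 153 without water replicate 5, and 236, 189 and 97 without 50 ppm replicates 1, 2 and 4. Egr1, Ccn1, Fos and Sgms1 kept their call in each of the 10 fits that left out 1 array. The call was lost in 9 of these fits for Cldn19, in 8 for Cidea, Nr4a1 and Ccna1, in 7 for Cenpq, Cmah, Gria1 and Mt2, in 6 for Klf15, Cd209c, Lrch2 and Igkv15-103, in 5 for Cdsn and Traf3ip3, in 4 for Efcab3 and Kdm4d and in 2 for Emb and Hmox1.

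**Figure D1:**
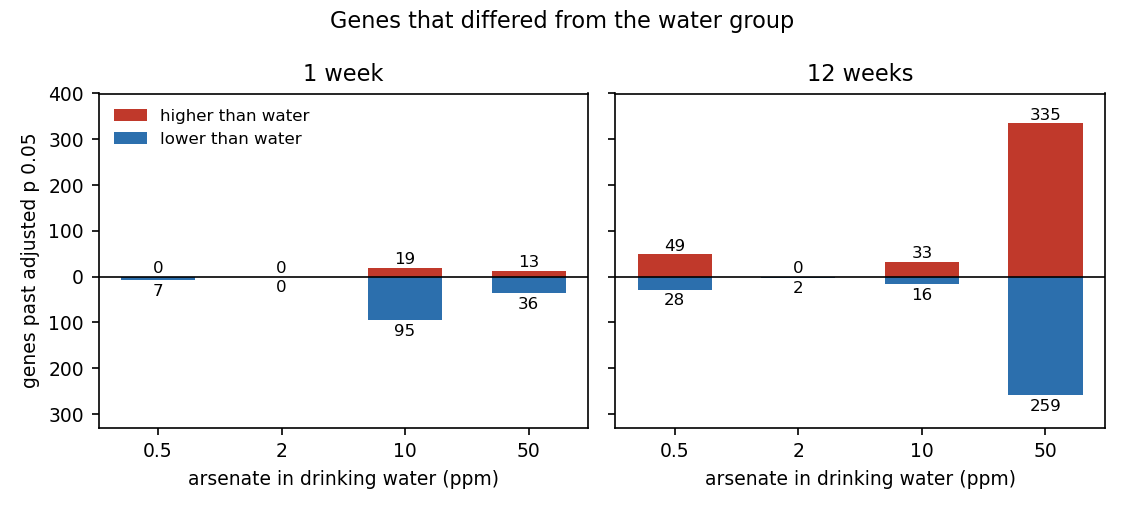
Number of genes called by limma (adjusted p under 0.05) at each arsenate dose in ppm against water, higher and lower genes apart, after 1 week and 12 weeks. The tallest bars are those of 50 ppm at 12 weeks, with 335 higher and 259 lower genes, and 2 ppm gave 0 genes at 1 week and 2 at 12 weeks.

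At 10 ppm and 12 weeks immediate early genes were also lower, against the same 5 water arrays. The mean of these genes in those arrays was 10.36, against 9.922 in the water arrays of 1 week. Egr1 fell by 2.82 ± 0.34 (adjusted p = 1.16e-04), Ccn1 by 2.40 ± 0.40, Fos by 1.49 ± 0.28 and the endothelial transcription factor Klf2 by 0.96 ± 0.21. Of 28 members 4 fell over all genes and 10 adjusted over the list alone, with a median change of -0.44 (camera adjusted p = 5.45e-08, and adjusted p = 0.616 with an estimated correlation). The largest rises were in Ccdc130 (1.31 ± 0.22), Pdia4 (0.93 ± 0.19), the transcriptional kinase Cdk12 (0.93 ± 0.16), Tpbg (0.89 ± 0.19) and the cohesin regulator Pds5a (0.86 ± 0.20), while the fibronectin receptor subunit Itga5 fell by 1.03 ± 0.23. Klf9 rose by 0.85 ± 0.19. Collagen and matrix genes were called lower by camera (median -0.23, adjusted p = 0.00128) with 0 of 28 members called over all genes and 3 lower adjusted over the list alone, and interferon response genes too (median -0.21, adjusted p = 0.0123) with 0 of 22 called either way. Both had adjusted p = 0.616 with an estimated correlation. In all 49 genes were called, 33 higher and 16 lower. The poly-A spike level was 1.05 lower than in water (exact permutation p = 0.00794, adjusted 0.0831) and hybridization controls were 0.542 higher (exact permutation p = 0.00794, adjusted 0.0831). With the poly-A covariate 22 genes were called, and leaving out 1 array moved the count between 9 without 10 ppm replicate 1 and 331 without water replicate 1, with 9 of 10 arrays moving it by over 1.5 times.

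At 2 ppm and 12 weeks 2 genes were called, Ccn1 (-2.52 ± 0.40, adjusted p = 0.00736) and Fos (-1.90 ± 0.28, adjusted p = 0.00482), both lower. Egr1 stood at -1.70 ± 0.34 (adjusted p = 0.124). Of 28 immediate early genes 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00413), and cell cycle genes were called higher (median 0.26, camera adjusted p = 0.00387) with 0 of 38 called over all genes or adjusted over the list alone. Both had adjusted p = 0.832 with an estimated correlation. The poly-A spike level was 0.486 below water (exact permutation p = 0.0317, adjusted 0.16), and 0 genes were called by limma with it as a covariate, against 1449 genes at an unadjusted p under 0.05 without it. The count was 1 without water replicate 5 and 5 without 2 ppm replicate 4.

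At 0.5 ppm and 12 weeks called rises included Cidea (1.80 ± 0.40), Cd209c (1.78 ± 0.36), Fam20a (1.54 ± 0.33), Cmah (1.45 ± 0.34) and Ccdc130 (1.18 ± 0.22). Cd209c rose from a water mean of 4.514, near the floor. The clock output gene Dbp fell by 1.19 ± 0.27, and Tmem229b, Tmem164, Sox15 and Krtcap3 fell by 0.70, 0.66, 0.64 and 0.62. Collagen and matrix genes were called higher (median 0.31, camera adjusted p = 7.07e-06), with 0 of 28 called over all genes and 10 higher and 1 lower adjusted over the list alone, and adjusted p = 0.337 with an estimated correlation. Smooth muscle markers were higher (median 0.26, camera adjusted p = 1.36e-04), with 1 of 14 risen over all genes and 6 adjusted over the list alone, and adjusted p = 0.323 with an estimated correlation. Markers of superficial and intermediate urothelium, the lining that faces the urine, were lower for 15 of 15 genes (median -0.23, camera adjusted p = 1.04e-05). Of these 0 were called over all genes and 8 fell adjusted over the list alone (adjusted p = 0.264 with an estimated correlation). Mesothelial markers were lower for 7 of 7 genes (median -0.46, camera adjusted p = 3.92e-04, adjusted p = 0.217 with an estimated correlation), 0 over all genes and 5 adjusted over the list alone. NRF2 targets were lower too (median -0.17, camera adjusted p = 0.00102, adjusted p = 0.264 with an estimated correlation), 1 of 29 over all genes and 2 adjusted over the list alone. Per array, smooth muscle markers were 0.368 higher than in water (exact permutation p = 0.0159, adjusted 0.108), skeletal muscle markers 0.295 higher (exact permutation p = 0.0238, adjusted 0.135), fibroblast markers 0.182 higher (exact permutation p = 0.0397, adjusted 0.186) and those of superficial and intermediate urothelium 0.221 lower (exact permutation p = 0.0238, adjusted 0.135). Limma called 77 genes, 49 higher and 28 lower. The count fell to 0 with the RNA integrity number as a covariate and to 4 with the poly-A covariate, and each of the 10 arrays moved it by over 1.5 times, from 0 without water replicate 5 to 485 without water replicate 1.

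Over the dose ranks of the 12-week harvest, Egr1 fell most steeply, by 0.80 ± 0.08 per rank (adjusted p = 7.84e-07, 25 arrays). Its mean log2 signal was 12.60, 12.05, 10.89, 9.78 and 9.73 from water to 50 ppm. Ccn1 fell by 0.65 ± 0.10 per rank, Nr4a1 by 0.56 ± 0.11, Fos by 0.41 ± 0.08 and Ccna1, a cyclin of the germ line, by 0.38 ± 0.09. The steepest rises were in T2 (0.33 ± 0.09), the repair factor Aplf (0.32 ± 0.09), Klf15 (0.30 ± 0.08, and 0.20 without water replicate 5), Thap6 (0.27 ± 0.08) and Klf9 (0.27 ± 0.04, adjusted p = 0.00146). In all 769 genes had a slope past the threshold, 428 rising and 341 falling. Limma called 0 genes with the poly-A covariate and 168 with the hybridization covariate, against 3294 at an unadjusted p under 0.05 without either. The count ran from 273 without water replicate 2, and also without 50 ppm replicate 4, to 1892 without 0.5 ppm replicate 1.

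**Figure D2:**
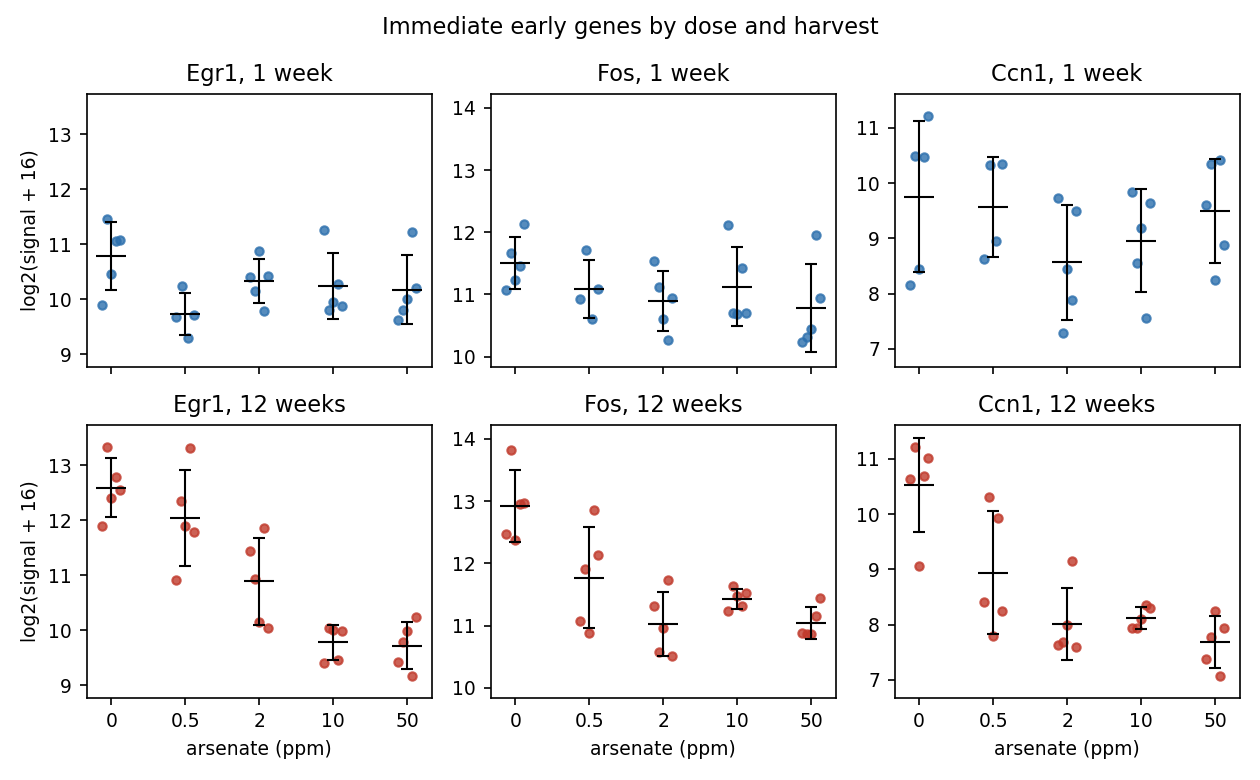
Log2(signal + 16) of immediate early genes in single arrays against arsenate dose in ppm, with group means and SD as bars, after 1 week and 12 weeks. Egr1 means at 12 weeks run from 12.60 in water to 9.73 at 50 ppm, and at 1 week from 10.79 in water to 10.18 at 50 ppm.

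**Figure D3:**
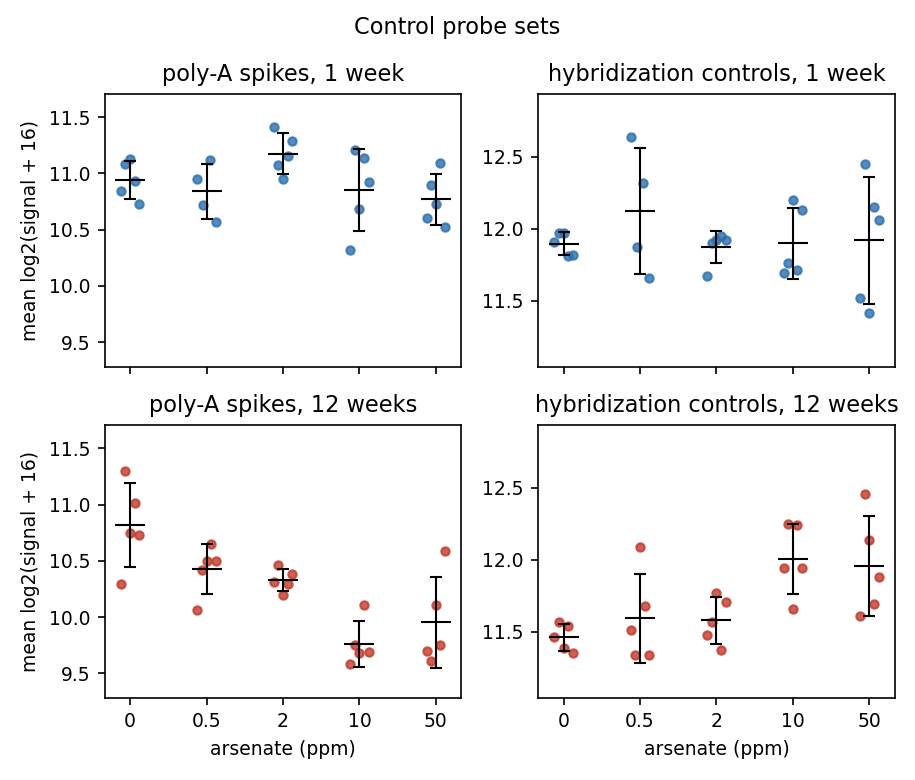
Mean log2(signal + 16) of the poly-A spike and hybridization control probe sets in single arrays against arsenate dose in ppm, with group means and SD as bars. At 12 weeks poly-A spikes average 10.81 in water and 9.763 at 10 ppm, and hybridization controls 11.46 and 12.01.

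After 1 week at 50 ppm transcripts typical of liver fell. Serpina1b, an alpha-1-antitrypsin, fell by 3.64 ± 0.69 (adjusted p = 0.0108), Serpina1c by 3.27 ± 0.69 and the fatty acid binding protein Fabp1 by 3.00 ± 0.63. Serum albumin, Alb (-2.885 ± 0.617, adjusted p = 0.0304), the fibrinogen chain Fga (-2.73 ± 0.49), plasminogen, Plg (-2.65 ± 0.48), and Cyp2d10 (-2.30 ± 0.41) fell with them. At 50 ppm Plg had a mean of 4.635 and Cyp2d10 of 4.48, near the floor, and Serpina1b of 5.047. The other probe set of Serpina1b stood at -2.94 and that of Fabp1 at -1.33. The mean of 23 liver markers per array was 6.395 against 7.97 in water, an exact permutation p of 0.0159 that was 0.108 adjusted. This mean holds 5 of the genes called lower in the same contrast, so its p is not separate support for their fall. Alb levels of the 5 water mice ran from 7.789 to 11.42. With the liver marker mean as a covariate 4 genes were called, but Serpina1b, Alb, Fga, Plg and Cyp2d10 are themselves part of this mean, so the covariate does not test their change.

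Apart from liver transcripts, Dnajb14, a chaperone of the endoplasmic reticulum, fell by 1.13 ± 0.14 (adjusted p = 2.96e-04) and stood at -1.22 (adjusted p = 0.0108) with the liver covariate. Krit1, which controls endothelial junctions, fell by 1.24 ± 0.19 (adjusted p = 0.00309), and the clock-linked repressor Nfil3 fell by 1.35 ± 0.23 (adjusted p = 0.00748). Other probe sets of Krit1 ran up to -0.07 and that of Dnajb14 to -0.11. Ndp, the Wnt receptor ligand norrin, rose by 0.98 ± 0.21, followed by Tmco4 (0.70 ± 0.13), the magnesium transporter Slc41a3 (0.70 ± 0.14), Rap1gap (0.59 ± 0.13), the palmitoyltransferase Zdhhc5 (0.58 ± 0.12), the phosphatase Cdc25b (0.58 ± 0.13), Irak2 (0.56 ± 0.10), Ppp6r1 (0.55 ± 0.12), Hsd17b2, which inactivates oestradiol (0.55 ± 0.11), and Gpat4 (0.50 ± 0.09). Probe sets of Slc41a3 and Zdhhc5 differed in sign, and the other probe set of Tmco4 stood at 0.19. The mesothelial marker Msln fell by 0.69 ± 0.15. With the liver covariate Dnajb14 was the 1 gene of the 20 named for their size, liver transcripts among them, that kept its call, and Krit1 stood at -1.23 ± 0.25 (adjusted p = 0.0737), Nfil3 at -1.25 ± 0.30 (adjusted p = 0.14), Slc41a3 at 0.89 ± 0.17 (adjusted p = 0.0667) and Ndp at 0.88 ± 0.28 (adjusted p = 0.248). Of all 49 called changes 24 were at least as large and 25 smaller with it, and their median SE went from 0.144 to 0.183. In the 10 fits that left out 1 array, the call was lost in 8 for Cdc25b, in 7 for Alb, Serpina1c, Ndp and Rap1gap, in 6 for Fabp1, Ppp6r1 and Zdhhc5, in 3 for Hsd17b2 and in 2 for Slc41a3.

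Immediate early genes were called lower here too (median -0.24, camera adjusted p = 2.04e-05), with 0 of 28 called over all genes, 5 lower adjusted over the list alone and adjusted p = 0.66 with an estimated correlation. Fos stood at -0.73 ± 0.30 (adjusted p = 0.335). NRF2 targets were called higher (median 0.15, camera adjusted p = 0.00788), 23 of 29 above water but 0 called over all genes or adjusted over the list alone, and adjusted p = 0.66 with an estimated correlation. Among them Srxn1 stood at 0.24 ± 0.09, Hmox1 at 0.22 ± 0.17, Nqo1 at 0.18 ± 0.12 and Gclm at -0.07 ± 0.09. Urothelial markers were higher (camera adjusted p = 0.0282), 1 of 15 adjusted over the list alone, and genes of epithelial to mesenchymal transition lower (camera adjusted p = 0.0104), 3 of 25 adjusted over the list alone, both with 0 called over all genes and adjusted p = 0.66 with an estimated correlation. Cell cycle genes were lower (median -0.18, camera adjusted p = 0.046, adjusted p = 0.81 with an estimated correlation), with 0 of 38 called either way. Fibroblast markers per array were 0.127 lower than in water (exact permutation p = 0.0159, adjusted 0.108), and the Gapdh 3' minus 5' signal, a measure tied to RNA quality, was 0.128 lower (exact permutation p = 0.00794, adjusted 0.0831). As3mt stood at 0.01 ± 0.12, Mt1 at -0.08 ± 0.11, Mt2 at 0.03 ± 0.12 and Cdkn1a at -0.03 ± 0.11, and As3mt, Mt1, Mt2 and Cdkn1a turned sign in some of the fits that left out 1 array. Limma called 49 genes, 13 higher and 36 lower. The count was 23, 29 and 30 without water replicates 2, 3 and 5, and 82 and 27 without 50 ppm replicates 2 and 3.

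**Figure D4:**
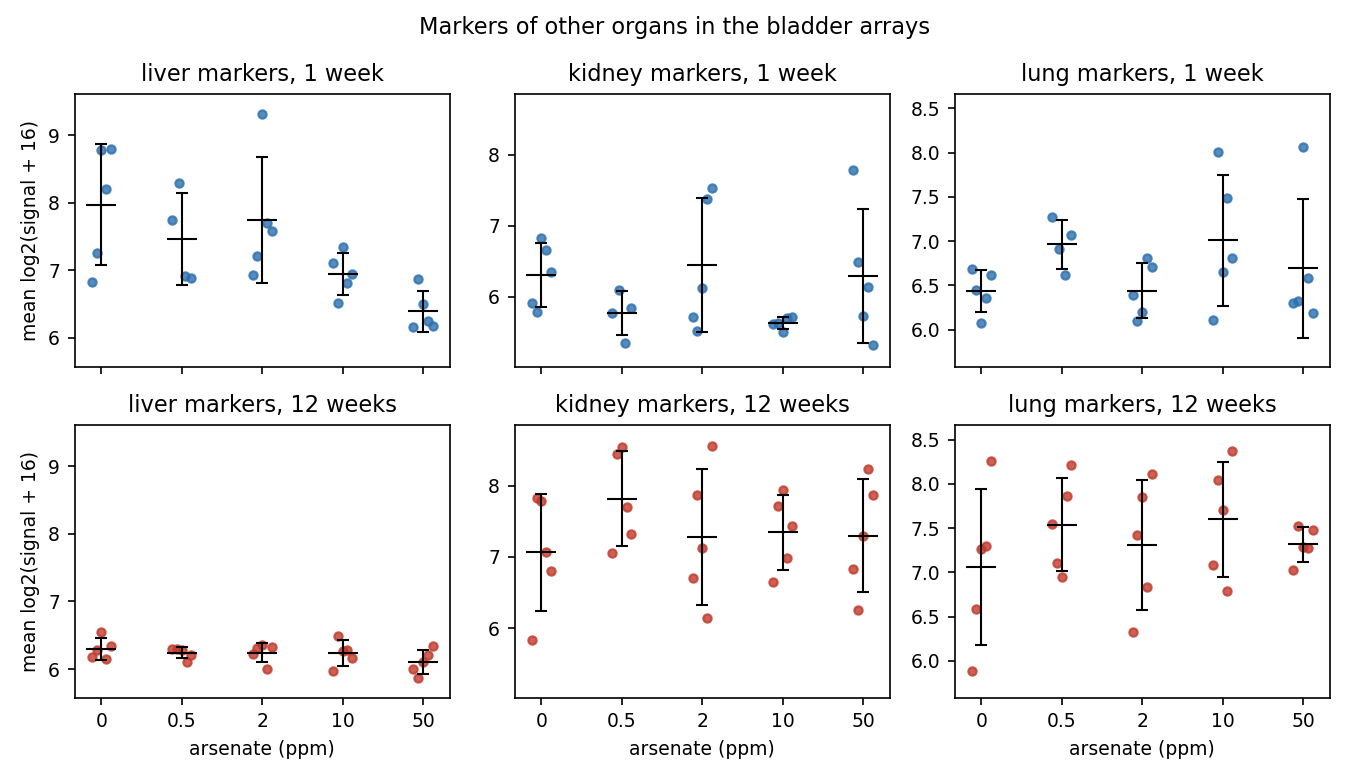
Mean log2(signal + 16) of liver, kidney and lung markers in single bladder arrays against arsenate dose in ppm, with group means and SD as bars, after 1 week and 12 weeks. Liver markers average 7.97 in water and 6.395 at 50 ppm at 1 week, and 6.295 in water at 12 weeks.

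At 10 ppm and 1 week, Il1f10, an interleukin-1 family cytokine (1.28 ± 0.29), Ivl, the cornified envelope protein involucrin (0.98 ± 0.20), Klhl14 (0.98 ± 0.18), the muscle calcium pump Atp2a1 (0.97 ± 0.23) and Lipo3 (0.69 ± 0.17) rose most. Cyp2d10 (-1.84 ± 0.41), Fam107a (-1.66 ± 0.34), Fxyd7 (-1.33 ± 0.32), the TWEAK receptor Tnfrsf12a (-1.28 ± 0.27) and the matricellular protein Ccn2 (-1.09 ± 0.26) fell. Cyp2d10 had a 10 ppm mean of 4.941, near the floor. The growth factor receptor Pdgfrb (-0.77 ± 0.13), the clock-linked protease Usp2 (-0.97 ± 0.20), and the glucocorticoid targets Cebpd (-0.77 ± 0.14) and Errfi1 (-0.48 ± 0.11) also fell. Immediate early genes were called lower, 1 of 28 over all genes and 7 adjusted over the list alone (camera adjusted p = 5.06e-05), as were glucocorticoid targets, 2 of 15 and 4 adjusted over the list alone (camera adjusted p = 0.00621), both with adjusted p = 0.483 with an estimated correlation. Collagen and matrix genes were lower, 0 of 28 over all genes and 4 adjusted over the list alone (camera adjusted p = 1.48e-04, adjusted p = 0.514 with an estimated correlation). Epithelial junction genes were higher, 0 of 23 over all genes and 6 adjusted over the list alone (camera adjusted p = 0.00369, adjusted p = 0.504 with an estimated correlation). Per array, markers of basal urothelium were 0.235 higher than in water (exact permutation p = 0.00794, adjusted 0.0831), those of superficial and intermediate urothelium 0.122 higher (exact permutation p = 0.0397, adjusted 0.186) and smooth muscle markers 0.206 lower (exact permutation p = 0.0476, adjusted 0.209). Probe sets for 18S ribosomal RNA were 1.28 lower than in water and kidney markers 0.673 lower, each with an exact permutation p of 0.00794, 0.0831 adjusted. Limma called 114 genes, 19 higher and 95 lower, and under quantile normalization 54 higher and 141 lower, 27.7% against 16.7% higher. The count was 2 with the liver covariate. It was 736 with the RNA integrity number as a covariate, a fit that leaves out the 2 arrays of 10 ppm without this number, and 437 with these 2 arrays left out and no covariate. Leaving out single arrays, 9 of 10 arrays moved it by over 1.5 times, from 20 without 10 ppm replicate 4 to 437 without 10 ppm replicate 1.

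At the other doses of 1 week few genes passed. At 0.5 ppm, with 4 arrays, limma called 7 genes, all lower, among them Tmem200c (-1.22 ± 0.21), Pdgfrb (-0.88 ± 0.13, adjusted p = 0.00689), the membrane anchor Ank1 (-0.84 ± 0.17), Fbxl7 (-0.71 ± 0.12) and the glycogen-targeting subunit Ppp1r3c (-0.68 ± 0.12). Their number ran from 0 without 0.5 ppm replicate 3 to 34 without 0.5 ppm replicate 4. At 2 ppm limma called 0 genes and 867 lay at an unadjusted p under 0.05. Matk (-1.44 ± 0.29), Ephb3 (-0.49 ± 0.10) and Gadd45g (-0.73 ± 0.16) had the smallest p, each with an adjusted p of 0.24. Camera called immediate early genes lower and cell cycle genes higher at 2 ppm, each with adjusted p = 2.05e-09, while adjusted p = 0.238 and adjusted p = 0.43 with an estimated correlation. Adjusted over the list alone 1 immediate early gene fell and 2 cell cycle genes rose, and 0 of either over all genes. The 2 ppm arrays had the lowest RNA integrity, and their 18S probe sets differed from water by -0.943 (exact permutation p = 0.0159, adjusted 0.108). The dose trend at 1 week gave 39 genes, 8 rising and 31 falling, led by Serpina1b (-0.83 ± 0.16 per rank), Serpina1c (-0.76 ± 0.17), Fabp1 (-0.74 ± 0.15), Cyp2d10 (-0.65 ± 0.10, near the floor at 50 ppm) and Fga (-0.65 ± 0.11), with Tmco4 (0.15 ± 0.03), Zdhhc5 (0.14 ± 0.03), Hsd17b2 (0.13 ± 0.03), Gpat4 (0.10 ± 0.02) and Usp48 (0.09 ± 0.02) rising. Limma called 0 trend genes with the liver covariate, of which Serpina1b, Cyp2d10 and Fga are part, against 1421 at an unadjusted p under 0.05 without it, and the count ran from 10 without 50 ppm replicate 3 to 83 without 50 ppm replicate 2.

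Whether the response depended on the length of exposure was tested as the difference between harvests, which also differ in the age of the mice and the day of collection. The 50 ppm effect was more negative at 12 weeks for Ccn1 (-2.58 ± 0.74) and Egr1 (-2.26 ± 0.48, adjusted p = 0.00469), followed by Clcn5 (-2.30 ± 0.71), Akap4 (-2.23 ± 0.58) and Opalin (-2.12 ± 0.65). Fos differed by -1.15 ± 0.44 without passing the test (adjusted p = 0.0917). It was more positive at 12 weeks for Serpina1b (3.60 ± 0.82), Alb (2.97 ± 0.75), Plg (2.69 ± 0.61), Gnmt (2.66 ± 0.76) and Fga (2.60 ± 0.64), all abundant in liver. Of these genes Serpina1b, Plg, Gnmt and Akap4 had their lowest group mean near the floor, at 4.682, 4.58, 4.69 and 4.697. For Egr1 the water arrays ran from 9.898 to 11.46 at 1 week and from 11.89 to 13.34 at 12 weeks. Its 50 ppm arrays ran from 9.628 to 11.23 and from 9.174 to 10.25. The water groups thus lay further apart than the 50 ppm groups. Serpina1b averaged 5.047 at 50 ppm and 1 week, and 4.728 in water and 4.682 at 50 ppm at 12 weeks. Its difference thus rests on the 1-week water arrays. Camera called 5 lists more positive and 0 more negative, led by smooth muscle markers, of which 3 of 14 were called over all genes and 4 adjusted over the list alone (adjusted p = 4e-04). Cell cycle genes followed, 5 of 38 over all genes and 6 adjusted over the list alone (adjusted p = 0.00206). With an estimated correlation the adjusted p was 0.774 and 0.904. Immediate early genes were not called (camera adjusted p = 0.102), and 3 of 28 were more negative over all genes and adjusted over the list alone. In all 1076 genes differed at 50 ppm, 527 more positive and 549 more negative, and 1448 genes differed at some dose by the F test, with Ppox, Foxo3, Zfp871, Gsk3b and Ywhaz at the smallest p. The 50 ppm count was 92 with the poly-A covariate, and ran from 484 without 12-week water replicate 2 to 1799 without 12-week water replicate 1.

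Across the 14624 genes, which are not independent replicates, changes at 10 and 50 ppm at 12 weeks had a correlation of 0.689. Both share the water arrays, and simulated unchanged groups gave a mean of 0.492, with 6 of 200 simulations as high. The covariance was 0.0684 against 0.0291 simulated, and with the water arrays split the correlation averaged 0.283. Of the called genes 27 were higher and 11 lower at both doses, with no simulated number to set them against. These included Egr1, Ccn1 and Fos among the lower genes. At 1 week the same doses had a correlation of 0.392 against 0.491 simulated, a covariance of 0.0302 against 0.0236, a split-water value of 0.11 and 8 genes lower at both. For 0.5 and 10 ppm at 1 week the correlation was 0.698 against 0.475 simulated, with 1 of 200 simulations as high, a covariance of 0.054 against 0.0241 and a split-water value of 0.352. For the other pairs of doses within a harvest, 27 to 184 of 200 simulations were as high. Between harvests, which share no array, the 50 ppm changes had a correlation of -0.207, and 0 called genes were higher at both or lower at both, where independent lists would share 0.298 and 0.638. At an unadjusted p under 0.05 limma held 1689 genes at 1 week and 3528 at 12 weeks.

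The water groups give the background between harvests, in which age, collection day and array processing cannot be told apart. Array measures differed too, with p adjusted over 16 measures. From 1 week to 12 weeks hybridization controls went from 11.9 to 11.46 (exact permutation p = 0.00794, adjusted 0.0254), 18S probe sets from 9.307 to 8.307 (exact permutation p = 0.0159, adjusted 0.0318), the Actb 3' minus 5' signal from 0.2676 to 0.3297 (exact permutation p = 0.0159, adjusted 0.0318) and that of Gapdh from -0.357 to -0.5472 (exact permutation p = 0.0317, adjusted 0.0564). Fibroblast markers per array were 0.541 lower and smooth muscle markers 0.463 lower (each exact permutation p = 0.00794, adjusted 0.0254). Markers of superficial and intermediate urothelium were 0.189 higher (exact permutation p = 0.0159, adjusted 0.0318) and those of basal urothelium 0.262 higher (exact permutation p = 0.0397, adjusted 0.0635). Collagen and matrix genes fell from 1 week to 12 weeks, 21 of 28 over all genes and 22 adjusted over the list alone, among them Eln (-1.78 ± 0.24), Col1a1 (-1.71 ± 0.23) and Col5a2 (-1.52 ± 0.18). The camera adjusted p was 1.4e-22, and the adjusted p was 0.0572 with an estimated correlation. Fibroblast markers fell, 7 of 11 over all genes and 9 adjusted over the list alone, such as Pdgfrb (-1.05 ± 0.15), with camera adjusted p = 3.75e-07 and adjusted p = 0.0572 with an estimated correlation. Cell cycle genes fell, 12 of 38 over all genes and 16 adjusted over the list alone, with the mitotic regulators Birc5 (-2.24 ± 0.47) and Cdk1 (-1.39 ± 0.27), camera adjusted p = 2.69e-08 and adjusted p = 0.209 with an estimated correlation. NRF2 targets rose, 8 of 29 over all genes and 12 adjusted over the list alone, with the glutathione transferases Gsta2 (0.72 ± 0.15) and Gsta3 (0.65 ± 0.11), camera adjusted p = 3.18e-05 and adjusted p = 0.11 with an estimated correlation.

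Immediate early genes were higher in the older water mice, 7 of 28 over all genes and 11 adjusted over the list alone (camera adjusted p = 0.00414, adjusted p = 0.525 with an estimated correlation). Egr1 rose by 1.81 ± 0.34, Nr4a1 by 1.70 ± 0.47, Atf3 by 1.45 ± 0.47 and Fos by 1.41 ± 0.31. Smooth muscle markers fell, 7 of 14 over all genes and 10 adjusted over the list alone (camera adjusted p = 8.04e-07, adjusted p = 0.209 with an estimated correlation). Epithelial junction genes rose, 9 of 23 over all genes, while 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0023, adjusted p = 0.291 with an estimated correlation), and the urothelial differentiation factor Grhl3 rose by 0.65 ± 0.11. Other called rises included Tesmin (2.07 ± 0.39), Kcna7 (1.72 ± 0.52), Akr1cl (1.52 ± 0.40), Prss44 (1.51 ± 0.38), Bcan (1.44 ± 0.39) and Mospd4 (1.36 ± 0.38). Liver transcripts were lower at 12 weeks, Serpina1b (-3.96 ± 0.58), Alb (-3.56 ± 0.53), Serpina1c (-3.43 ± 0.57), Cyp3a11 (-2.84 ± 0.53), Fga (-2.81 ± 0.45), Plg (-2.71 ± 0.43), Apoa1 (-2.69 ± 0.53), Fabp1 (-2.52 ± 0.52), Hpx (-2.42 ± 0.46) and Apoc4 (-2.29 ± 0.53). Liver tissue or RNA carried into 1-week samples, taken up below, may account for these differences. Within groups 19 of 22 liver markers other than Alb followed Alb with r over 0.5 at 1 week, and 2 of 22 at 12 weeks. The 1-week means of Akr1cl, Bcan and Mospd4 were 4.878, 4.813 and 4.5, and the 12-week means of Serpina1b, Plg and Apoc4 were 4.728, 4.58 and 4.785, all near the floor. In all 1953 genes differed, 916 higher and 1037 lower at 12 weeks. With the liver covariate, which is built from liver transcripts and so does not test their change, 294 were called.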

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

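Tests chosen after the result was seen are the poly-A spike and collection order tests for the immediate early genes and the test of arsenate lowering liver transcripts, and the poly-A spike and hybridization covariates of the other tests were chosen after the data, though not the covariate fits, had been seen.

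Single arrays far from the others of their group were found in 13 of 189 groups of values, and chance gives about 1 in 20. At 12 weeks, 0.5 ppm replicate 1 had an array median of 7.085 (others 6.927 to 6.956), a first principal component of -45.24 (others 0.1716 to 18.14) and a median correlation with its own group of 0.9558 (others 0.9751 to 0.9779). The 10 ppm replicate 4 of that harvest had a first component of 23.06 (others -15.85 to -7.582) and a correlation of 0.965 (others 0.9741 to 0.9771). Water replicate 2 had an array median of 6.689 (others 6.932 to 6.97). The other 7 values each stood alone. At 12 weeks they were an RNA integrity number of 9.8 in 2 ppm replicate 2 (others 9.6), a Gapdh 3' minus 5' signal of -0.4028 in 0.5 ppm replicate 5 (others -0.5542 to -0.5175) and a smooth muscle marker mean of 13.08 in 0.5 ppm replicate 2 (others 13.32 to 13.38). At 1 week they were hybridization controls of 11.67 in 2 ppm replicate 1 (others 11.9 to 11.95), an Actb 3' minus 5' signal of 0.2997 in water replicate 2 (others 0.2518 to 0.2638), lung markers of 8.068 in 50 ppm replicate 3 (others 6.187 to 6.581) and basal urothelium markers of 10.77 in 2 ppm replicate 4 (others 11.13 to 11.25).

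The 50 ppm effect differed between harvests for 1076 genes, and 1448 genes differed at some dose. By the test of the difference itself, Serpina1b (3.60), Alb (2.97), Plg (2.69), Gnmt (2.66) and Fga (2.60) were more positive at 12 weeks, and Ccn1 (-2.58), Clcn5 (-2.30), Egr1 (-2.26), Akap4 (-2.23) and Opalin (-2.12) more negative. For Egr1 and Serpina1b the water groups of the harvests lay further apart than the 50 ppm groups. Outside the gene measurements, hybridization controls at 12 weeks were 0.542 above water at 10 ppm and 0.494 above water at 50 ppm.

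Other splits of the samples into groups of the same sizes were counted, 100 for each result with the real split included. At 1 week, 1 of the 100 splits called as many genes at 0.5 ppm (7 genes, highest other 2), 100 at 2 ppm (0 genes, highest other 16), 1 at 10 ppm (114 genes, highest other 42) and 2 at 50 ppm (49 genes, highest other 125). At 12 weeks the counts were 3 splits at 0.5 ppm (77 genes, highest other 192), 2 at 2 ppm (2 genes, highest other 11), 2 at 10 ppm (49 genes, highest other 1190) and 2 at 50 ppm (594 genes, highest other 1063). For the dose trends they were 1 at 1 week (39 genes, highest other 1) and 2 at 12 weeks (769 genes, highest other 2022). They were 1 for the 50 ppm difference between harvests (1076 genes, highest other 293), 1 for the F test (1448 genes, highest other 2) and 1 for the water groups (1953 genes, highest other 924). For each result except 2 ppm at 1 week, 1 to 3 of the 100 splits, the real one included, called as many genes. So high a count was rare among the splits. With 100 splits each and no adjustment over the results, chance is not excluded. At 2 ppm and 1 week limma called 0 genes and 867 lay at an unadjusted p under 0.05. Some splits called several times the real count, as with 1190 genes against 49 at 10 ppm and 12 weeks, and the reason was not tested.

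The genes called at 50 ppm and 12 weeks shifted by 1.23 ± 0.17 in a score per array, the mean of the higher genes minus the mean of the lower genes. With the hybridization controls as a covariate 108% of the shift was kept (1.33 ± 0.208). Within groups the score had no clear relation to these controls (r = -0.186, permutation p = 0.447). This argues against a hybridization effect that also acts within groups as the whole cause. It cannot test a difference between whole groups that leaves no trace within them. The genes of the score were also chosen from this same contrast. A difference read from the poly-A spikes, such as one in labelling, stays open. With the spike level as a covariate 59.9% was kept (0.735 ± 0.203). Within groups the score followed the spike level (r = -0.606, rho = -0.541, permutation p = 0.00202, r = -0.63 without the 2 farthest, 25 arrays). Each array had been scaled to a common mean, so the spike level is relative to the other signal of the array. It cannot tell a labelling difference from a difference in the RNA of the sample. Arsenate stays open too, as the slope per dose rank over the 0.5, 2 and 10 ppm arrays was 0.0986 ± 0.0927 (permutation p = 0.31). Dose and spike level moved together, so they cannot be told apart for these genes, of which 71 of 594, Cidea and Cd209c among them, had a change at least as large with the spike covariate.

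The immediate early genes were lower at 50 ppm and 12 weeks by a mean of -0.719 ± 0.223 per array. With the hybridization covariate 95.1% was kept (-0.683 ± 0.278), and within groups the relation was weak (r = -0.0507, permutation p = 0.819). This argues against a hybridization effect that also acts within groups as the whole cause. It cannot test a difference between whole groups that leaves no trace within them. With the poly-A spike covariate 30.8% was kept (-0.222 ± 0.297), and within groups their mean followed the spike level (r = 0.465, rho = 0.463, permutation p = 0.0133, r = 0.399 without the 2 farthest, 25 arrays). The order or time of tissue collection stays open. The first number of the labels, 1 per group, rose with dose in both harvests (Spearman rho = 1). Whether it gives an order of collection is not stated. Within groups the mean correlation among the 28 genes was 0.479, above 100% of 10000 random lists matched on level (random median 0.00423). Genes that respond together would correlate whatever made them vary, so this correlation cannot decide the question. The labels give no order within groups, as all mice of a group share this first number. These explanations and an effect of arsenate cannot be told apart, because spike level and dose moved together and no order of collection is given.

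The liver transcripts that were lower at 50 ppm and 1 week may come from liver tissue or RNA carried into some samples. Within the 1-week groups 19 of the 22 markers other than Alb followed Alb with r over 0.5 (median r 0.813), against 2 of 22 at 12 weeks (median r 0.00873). Alb itself ranged from 5.91 to 12.5 at 1 week and from 5.02 to 7.49 at 12 weeks. Liver was collected from the mice of 1 week and is not named among the tissues of 12 weeks. The marker mean ranged over 1.96 among the 5 water arrays of 1 week, so it varied widely without arsenate. From water to 50 ppm its group means at 1 week were 7.97, 7.461, 7.745, 6.949 and 6.395. Its highest single value, 9.315, was in 2 ppm replicate 3. An added effect of arsenate on liver genes expressed by the bladder stays open, because so wide a spread cannot decide it.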

How the results depend on the processing

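Covariates for the poly-A spikes, the hybridization controls and the liver markers, and the fits without 3 outlying arrays or without the 2 arrays that lack an RNA integrity number, were chosen after seeing the data. The limits are 4 or 5 mice per group, signals near background that the offset compresses, and at 12 weeks a spike level that moves with dose. Named genes at 50 ppm kept their call in each fit that left out 1 array for 10 of 20 genes at 1 week and 4 of 22 at 12 weeks. Where no reason is given, the cause was not tested.

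With quantile normalization 13 genes were called at 0.5 ppm and 195 at 10 ppm at 1 week, and oxidative phosphorylation genes at 0.5 ppm and 12 weeks changed direction (adjusted p = 0.67). Without a filter 72 were called at 10 ppm and 1 week. With the filter at the 60th percentile, which tests fewer genes, 17 were called at 0.5 ppm at 1 week, and 155 at 0.5 ppm and 75 at 10 ppm at 12 weeks. With all probe sets, which tests more features, the counts were 585 at 10 ppm and 598 at 50 ppm at 1 week, and 119, 4, 299 and 1256 at 0.5, 2, 10 and 50 ppm at 12 weeks. They were 489 and 1616 for the trends at 1 and 12 weeks, 2271 for the 50 ppm difference between harvests, 3023 for the F test and 4191 for the water groups.

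Array weights gave 401, 2, 1262 and 248 genes at 0.5, 2, 10 and 50 ppm at 1 week, 534, 497 and 1331 at 0.5, 10 and 50 ppm at 12 weeks, 116 and 1732 for the trends, 3382 for the F test and 3219 for the water groups. A minimum of 1.5-fold, which only removes genes, left 71 at 10 ppm and 1 week, 46, 31 and 257 at 0.5, 10 and 50 ppm at 12 weeks and 765 for the water groups. All 49 arrays in 1 fit gave 4 at 0.5 ppm and 1 week, and 459, 1, 226 and 1187 at 0.5, 2, 10 and 50 ppm at 12 weeks. With the RNA integrity number as a covariate, limma called 11 and 736 at 0.5 and 10 ppm at 1 week, 0, 29 and 285 at 0.5, 10 and 50 ppm at 12 weeks and 60 for the 1-week trend, where 0 stands against 2778 genes at an unadjusted p under 0.05 without it. This fit leaves out the 2 arrays without a number, replicates 1 and 2 of 10 ppm at 1 week, so at 1 week the covariate and the arrays change together. Without these 2 arrays and with no covariate, limma called 9 and 437 at 0.5 and 10 ppm, 34 for the 1-week trend and 1063 for the difference between harvests. Adipocyte markers at 2 ppm and 1 week changed direction with the covariate (adjusted p = 0.852), but not with these 2 arrays left out and no covariate.

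With the poly-A spike covariate 74 genes were called at 10 ppm and 1 week, and 4, 0, 22 and 1 at 0.5, 2, 10 and 50 ppm at 12 weeks. Limma called 25 and 0 for the trends at 1 and 12 weeks, where 1421 and 3294 lay at an unadjusted p under 0.05 without it, and 92 for the difference between harvests. As3mt at 50 ppm and 1 week changed sign to -0.01738, and at 12 weeks Mt1 to 0.1712 and Cdkn1a to 0.2345. With the hybridization covariate 41 were called at 0.5 ppm and 1 week, 17 at 10 ppm and 12 weeks and 168 for the 12-week trend, and at 50 ppm and 12 weeks As3mt changed sign to 0.07478 and Gclm to -0.001509. With the liver covariate 2 and 4 were called at 10 and 50 ppm at 1 week, 0 for that trend and 294 for the water groups. It turned As3mt to -0.0019, Mt1 to 0.00571 and Cdkn1a to 0.1006 at 50 ppm and 1 week, and Fabp1 between the water groups to 0.02239. The covariate is built from liver transcripts, so it does not test their change. The 3 outlying arrays were 50 ppm replicate 2 of 1 week (first principal component 55.38, others of its group -14.04 to 22.24) and water replicate 2 and 0.5 ppm replicate 1 of 12 weeks, so within 1 week the first alone was left out. This first array was not flagged by the rule for single arrays used above. The 10 ppm replicate 4 of 12 weeks, flagged for its first component and its correlation with its group, was kept. Without the 3 arrays 37, 474 and 82 were called at 0.5, 10 and 50 ppm at 1 week, 83 for that trend and 410 for the difference between harvests, and Mt2 at 50 ppm and 1 week turned to -0.02354.

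Camera called 71 lists with the preset correlation and 0 with an estimated correlation, 76 with quantile normalization and 78 with the integrity covariate. With the water arrays split between both doses, the correlations of dose effects at 1 week were 0.149 for 0.5 and 2 ppm, 0.352 for 0.5 and 10 ppm, 0.0164 for 0.5 and 50 ppm, 0.222 for 2 and 10 ppm, 0.0649 for 2 and 50 ppm and 0.11 for 10 and 50 ppm. At 12 weeks, in that order, they were 0.176, 0.0782, 0.231, 0.0987, 0.2 and 0.283.

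With the replicate number as a block 2 and 74 genes were called at 0.5 and 10 ppm at 1 week. Arrays of the same replicate number had a mean correlation of -0.0101 at 1 week and 0.0181 at 12 weeks after removing group means, and 4 of 24 and 8 of 25 arrays were closest to their own number, so the block carries no known pairing.

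Leaving out 1 array moved the counts as follows, lowest to highest. At 1 week they ran from 0 to 34 at 0.5 ppm, 0 to 0 at 2 ppm, 20 to 437 at 10 ppm, 23 to 82 at 50 ppm and 10 to 83 for the trend. At 12 weeks they ran from 0 to 485 at 0.5 ppm, 1 to 5 at 2 ppm, 9 to 331 at 10 ppm, 47 to 1617 at 50 ppm and 273 to 1892 for the trend. The difference between harvests ran from 484 to 1799, the F test from 1002 to 2123 and the water groups from 1335 to 2058. Where these counts reach 0, limma held 1823, 867 and 2778 genes at an unadjusted p under 0.05 with every array, at 0.5 and 2 ppm at 1 week and 0.5 ppm at 12 weeks. At 50 ppm and 1 week Cdkn1a ran from -0.07926 to 0.007287, Mt2 from -0.02476 to 0.111, Mt1 from -0.1827 to 0.001928 and As3mt from -0.04668 to 0.05721. The arrays behind the extremes at 12 weeks and 50 ppm were water replicate 2 (47) and water replicate 1 (1617).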

Other observations

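Single members of other lists changed at 50 ppm and 12 weeks. The core clock activator Clock rose by 0.75 ± 0.19 and the endothelial receptor Tie1 by 0.90 ± 0.25. The junction protein plakoglobin, Jup, fell by 0.66 ± 0.16, the hypoxia target Ankrd37 by 0.52 ± 0.15, the mesothelial marker Lrrn4 by 0.59 ± 0.17 and the co-chaperone Fkbp4 by 0.28 ± 0.08. Each was the 1 called member of its list over all genes, and camera called none of these lists. The epithelial junction list had a median of 0.03 and a mean of -0.03, and its test pointed down (adjusted p = 0.824).

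At 0.5 ppm and 1 week, camera called 5 lists higher and 7 lower. Collagen and matrix genes were lower for 25 of 28 genes (median -0.26, camera adjusted p = 1.2e-06), with 0 over all genes and 3 adjusted over the list alone, and urothelial markers were higher for 15 of 15 (median 0.20, camera adjusted p = 1.13e-05) with 0 called either way. Both had adjusted p = 0.334 with an estimated correlation. Per array, fibroblast markers were 0.196 lower than in water and markers of superficial and intermediate urothelium 0.203 higher, and the first principal component differed by -17.4, each with an exact permutation p of 0.00794, 0.0831 adjusted. Skeletal muscle markers were 0.199 lower and lung markers 0.53 higher, each with an exact permutation p of 0.0317, 0.16 adjusted. The collagen and matrix list and the urothelial list moved the opposite way at 0.5 ppm and 12 weeks, a difference that was not tested. At 2 ppm and 1 week macrophage and dendritic cell markers were lower (median -0.08, camera adjusted p = 1.95e-05), 0 of 14 over all genes and 5 adjusted over the list alone, with adjusted p = 0.43 with an estimated correlation.

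Transcripts of other organs varied between bladders of both harvests. Kap, an abundant kidney transcript, ranged from 6.47 to 11.4 at 1 week and from 7.03 to 12.9 at 12 weeks. Of 10 other kidney markers, 6 followed it at 1 week and 9 at 12 weeks with r over 0.5 within groups. The lung surfactant gene Sftpc ranged from 5.45 to 9.72 and from 5.76 to 10.4, and 4 of 7 and 5 of 7 other lung markers followed it.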
